A study of Mus musculus with 26 samples.

How the data were processed

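Single retinal cells of mice homozygous for a floxed Notch1 allele were profiled on Affymetrix mouse expression arrays, with 1 cell per array. Per the labels' protocols, retinas were electroporated in vivo at postnatal day 0 and collected at postnatal day 3. Control cells (WT) received a plasmid that drives GFP from the ubiquitous CAG promoter. Cells of the knockout group (N1-CKO) received CAG-driven Cre recombinase, which deletes the floxed part of Notch1, together with a GFP reporter that Cre switches on. Retinas were dissociated, and GFP-positive cells were picked by hand under a fluorescence microscope and lysed 1 per tube. Per the same protocols, first-strand cDNA was made with modified oligo dT primers, given a poly-A tract and amplified by PCR with the same primers, so that signal comes from near the 3' ends of transcripts. The 2 groups hold 13 cells each, 26 in all.

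The deposited values are array intensity on a linear scale, made by the authors with MAS5, per the submitters' processing notes. MAS5 combines the probes of each probe set into 1 signal and scales each array to a common mean. The values bear such a scaling out: the mean signal after trimming 2% from each end was 500.0 on every array. MAS5 detection calls were not used here. The version of MAS5 and its other parameters are not given in the sources used here. Because every array was scaled to the same mean, a difference in total RNA per cell cannot be read from these values, and an array with few bright probe sets shows each of them brighter.

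The table holds 45101 probe sets, of which 64 are array controls. GEO's platform annotation gave 1 gene symbol for 34958 probe sets and several for 932, which were left out of all gene values. A further 9160 probe sets that are not controls, and 51 of the controls, were not listed there and stay unnamed. Symbols were looked up through the Entrez number in a RefSeq gene table of assembly GRCm38.p6, and 0 of them needed another symbol. That table served for names only. No coordinates are given, because the genome build behind the array annotation is not given in the sources used here. This left 18193 genes.

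Signals below the pooled median of all arrays, 25.02 (log2 of 4.65), were raised to that value before log2 was taken. A gene counted as detected in a cell when its signal reached the 90th percentile of that cell's own array over the probe sets that are not controls, which makes 4504 probe sets per cell. This rule fixes the number of detected probe sets and says which transcripts were among the brightest, not how many were expressed. For a gene with several probe sets, the probe set with the highest mean log2 signal over the 26 cells was used. Of the 96 genes named, 19 had at least 1 other probe set with the opposite sign, 23 of 108 other probe sets in all. Apart from a probe set of Rbpj, these were detected in at most 3 cells of a group. Each difference is the mean log2 signal of N1-CKO cells minus that of WT cells. A transcript could be bright in some cells and near background in others. Such a difference therefore mixes in how many cells a transcript was detected with its level in them, which were not separated, and is no fold change within a cell.

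No test between the groups was made. The labels name no animal, litter or picking session, so that cells cannot be counted as independent replicates and each group stands as 1 sample. SDs describe the spread between cells. Intervals on shares of cells are exact Clopper-Pearson 95% intervals and cover counting error only. The number of arrays limits the precision of all values. For gene lists, the median difference over members detected in at least 2 of the 26 cells was set beside 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile and the central 95% of these random medians describe these 26 libraries and are no test of the genotype. Members that rise and fall together within cells, as cell cycle genes can, may move a list's median further than random lists allow for.

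The 21 gene lists, the definitions of detection and floor, all alternatives but those given as added later, and the rule for naming genes were fixed before the data were examined. By that rule, the genes named are the 12 highest and 12 lowest differences among genes detected in at least 6 cells whose number of detected cells differs in the same direction. Every member of the list of Notch receptors and effectors detected in at least 2 cells is also named, with up to 4 members of each other list that had the largest differences. Genes named outside the rule are given as such. The lists hold 291 genes, of which 270 were measured and 21 were not analysed here. Where a gene was detected in 0 cells of a group, a fold was given only as a bound, from the other group's mean over all its cells against the detection thresholds of the dim group's arrays, and only where it exceeded 1.

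Arrays were split into sets at the largest gap in the signal of the 18S ribosomal RNA control probe set, a split chosen after the data were seen. Differences were computed again within each set, and over the cells whose ratio of the 3' to the 5' Gapdh control probe set was at most 3, also chosen after the data were seen. Alternatives covered quantile normalization, scaling to the 75th percentile, other floors, medians over cells, other choices of probe set and of list members, other detection thresholds, leaving out WT cells 1 and 2, whose records are numbered apart from the rest, and leaving out each cell in turn.

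The steps were tested on simulated data in which each gene's signals were drawn again from its own pooled values and 200 bright genes were shifted. For the single genes difference, with 18193 genes, planted log2 shifts of -4, -2, 2 and 4 came back with medians of -3.79, -1.86, 2.13 and 3.91. For the gene lists difference, with 8029 genes, 90% of lists of 20 in which 10 members were shifted by -2, and 88% with 10 members shifted by 2, lay outside the random range on the planted side. Of 200 lists with 0 shifted members, 5% lay outside it. Each gene was drawn separately, so the simulated lists lack genes that rise and fall together within cells. The 5% therefore does not describe lists of such genes. The shifted genes were detected in most cells, unlike many of the genes named below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.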

Results

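The series asks which transcripts differ between postnatal retinal cells with and without Cre-mediated deletion of Notch1, a receptor that keeps retinal progenitors from differentiating. Cells of both groups carried the floxed allele, were marked by GFP after electroporation at birth and were collected 3 days later, when progenitors still divide and rods, bipolar cells, some amacrine cells and Müller glia are being made. There were 13 WT and 13 N1-CKO cells, each on its own array. Groups have no replicate animals in the labels, so all differences below compare these cells, without a test.

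The arrays of the groups overlapped in brightness. At a common threshold, a signal of 1252, WT cells had a median of 4764 bright probe sets (2558 to 6212) and N1-CKO cells 4433 (2800 to 5670). Log2 signals of any pair of cells correlated across probe sets with r between 0.20 and 0.64 (median 0.45), and no pair of profiles was identical. The 18S ribosomal RNA control split the arrays into a high 18S set of 5 WT and 5 N1-CKO cells, with 18S signals from 12106 to 93363, and a low 18S set of 8 and 8 cells, with signals from 26.9 to 2059. The high 18S arrays had fewer bright probe sets, with a median of 3641 against 5066. The ratio of the 3' to the 5' control probe set of Gapdh, which grows when cDNA is short or RNA is degraded, had a median of 1.79 in WT cells (1.40 to 3.26) and of 2.67 in N1-CKO cells (1.46 to 245). Its 5 highest values, from 3.43 to 245.4, were all in N1-CKO cells (4, 5, 6, 12 and 13), all on low 18S arrays. The same ratio for Actb had a median of 3.33 in WT cells (1.41 to 54.8) and of 4.78 in N1-CKO cells (0.857 to 2351). List values are therefore also given for the 11 WT and 8 N1-CKO cells with a Gapdh ratio of at most 3, a limit chosen after the ratios were seen. The limit keeps all 5 and 5 cells of the high 18S set but 6 WT and 3 N1-CKO cells of the low 18S set, so the sets are not balanced in these values. Because the 18S sets hold both groups in equal numbers, values within each set are given beside those of all cells. Equal numbers do not make the low 18S set balanced. There the ratio of 2 hybridisation controls, Cre over bioD, was 1.49 to 1.75 in WT cells 1 to 7 and 1.28 in WT cell 13. In N1-CKO cells of that set it was 1.07 to 1.47. In the high 18S set the groups overlapped, with 1.42 to 1.77 in WT and 1.58 to 1.83 in N1-CKO cells.

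Notch1 transcript was detected in 10 of 13 WT cells (76.9%, interval 46.2 to 94.96) and in 8 of 13 N1-CKO cells (61.5%, interval 31.6 to 86.1). Its mean log2 signal was 12.00 ± 3.06 (SD over cells) in WT and 10.35 ± 4.21 in N1-CKO cells, a difference of -1.65 that lies within the cell-to-cell spread. The difference was -0.40 in the high 18S set, -2.43 in the low 18S set and -0.09 over cells with a Gapdh ratio of at most 3. The other Notch1 probe set was dimmer, with 8.61 ± 2.17 against 7.34 ± 2.41, and was detected in 3 WT and 2 N1-CKO cells. The position of these 3' probe sets relative to the deleted part of the gene is not known here, and a probe set outside it says nothing about recombination. The arrays also carry a Cre control RNA added to every hybridisation, so that Cre itself cannot be read from them.

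Genes of G2/M and mitosis were lower in N1-CKO cells as a group. Of the 22 G2/M and mitosis genes used, 22 had lower means in N1-CKO cells, with a median difference of -3.43, below all 10000 matched random lists (central 95% of -0.81 to 0.58). WT cells had a median of 13 members detected (range 2 to 22) and N1-CKO cells 2 (range 0 to 13). At least 8 members were detected in 10 of 13 WT cells (76.9%, interval 46.2 to 94.96). The same held for 3 of 13 N1-CKO cells (23.1%, interval 5.04 to 53.8), so the intervals overlap. Averaged over members, log2 signal per cell was 10.10 ± 2.53 in WT and 6.89 ± 1.78 in N1-CKO cells, a difference larger than either SD. The proliferation antigen gene Mki67 was detected in 11 WT and 4 N1-CKO cells, with 12.57 ± 3.11 against 8.35 ± 4.48. Cdc20, an activator of the anaphase-promoting complex, was detected in 10 and 3 cells and differed by -4.36. The spindle gene Nusap1 (10 and 2 cells) differed by -5.72 and the chromatin gene Hmgb2 (8 and 1 cells) by -4.62. The list's median was -1.52 in the high 18S set and -4.16 in the low 18S set, in both cases below the random range. Over cells with a Gapdh ratio of at most 3 it was -2.79, again below all random lists, with Mki67 at -2.79 and medians of 13 members detected per WT cell and 3.5 per N1-CKO cell. With medians over cells in place of means it was -5.50.

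Genes of G1/S and DNA replication were lower as a group, though not uniformly. Of 20 members, 16 had lower and 4 higher means in N1-CKO cells, with a median of -2.16, below all random lists (central 95% of -0.82 to 0.65). WT cells had a median of 10 members detected (4 to 17) and N1-CKO cells 4 (1 to 13). Rrm1, the large subunit of ribonucleotide reductase, was detected in all 13 WT cells (100%, interval 75.3 to 100) and in 5 N1-CKO cells (38.5%, interval 13.9 to 68.4), with 13.23 ± 0.98 against 8.43 ± 3.71. Uhrf1, which maintains DNA methylation at replication, was detected in 7 WT and 0 N1-CKO cells. Mcm3, a subunit of the replicative helicase, differed by -3.30 and the ligase gene Lig1 by -3.16. The list's median in the high 18S set, -0.92, lay just below the random range there, which began at -0.85, and in the low 18S set it was -2.99. It stayed at -2.16 over cells with a Gapdh ratio of at most 3. It was -3.85 with medians over cells and -1.40 with the mean of all probe sets of a gene.

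**Figure D1:**
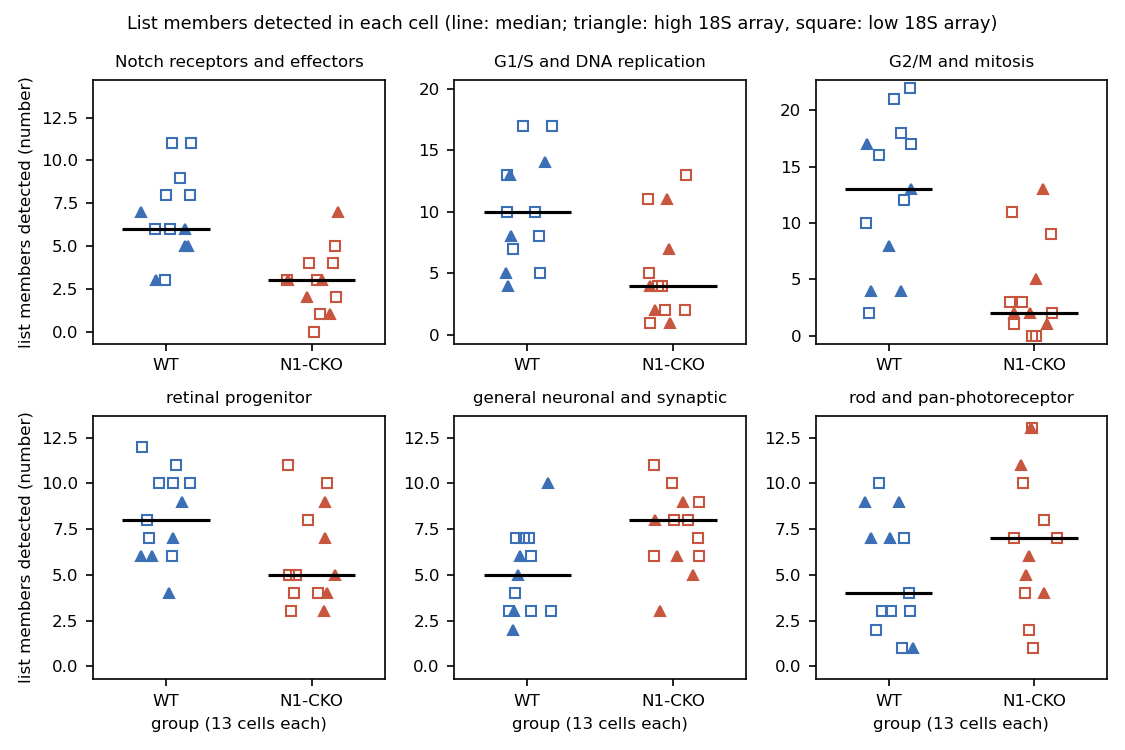
Number of list members detected (vertical axes) in each of 13 WT and 13 N1-CKO cells for 6 gene lists; each point is 1 cell, triangles are high 18S arrays, squares are low 18S arrays, and lines are medians. The median number of G2/M and mitosis members was 13 in WT and 2 in N1-CKO cells, and that of neuronal and synaptic members was 5 and 8.

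Of the 12 lowest single differences, Rrm1, Nusap1 and Hmgb2 belonged to the cell cycle lists and Id3 to the Notch list. The others included the GTPase-activating protein gene Arhgap11a (12 WT and 3 N1-CKO cells, -5.98), the spindle protein gene Tacc3 (11 and 2 cells, -5.37), Cdca3 (10 and 3 cells, -5.21), the Ran exchange factor Rcc1 (7 and 0 cells, -4.73), the chromosomal passenger gene Cdca8 (9 and 2 cells, -4.63) and the replication licensing inhibitor Gmnn (8 and 1 cells, -4.38). Etv5, an ETS transcription factor of the FGF pathway, was detected in 10 WT and 0 N1-CKO cells (0%, interval 0 to 24.7), with 10.75 ± 3.40 against 5.30 ± 1.46, and was at least 1.70-fold lower by its bound. For Rcc1 the bound was at least 1.02-fold lower. Id3, an inhibitor of basic helix-loop-helix factors, was detected in 12 and 3 cells (-5.02), and the phosphomannomutase gene Pmm1 in 7 and 1 cells (-4.37). Differences ranged from -6.15 (Pmm1) to -0.96 (Tacc3) in the high 18S set and from -8.13 (Tacc3) to -3.25 (Pmm1) in the low 18S set, and with medians over cells they reached -9.42 for Arhgap11a, -8.51 for Cdca3, -8.29 for Cdca8 and -7.53 for Gmnn. With the mean of all probe sets, Etv5 differed by -2.38, Cdca3 by -1.65, Rrm1 by -1.98, Tacc3 by -3.32, Nusap1 by -3.06 and Hmgb2 by -2.88, and a dim probe set of Etv5 (1 and 0 cells) had a difference of 0.24.

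None of the 12 highest differences was of a gene in the lists. Meg3, a maternally expressed long noncoding RNA, was detected in 3 WT and 12 N1-CKO cells, with 7.27 ± 3.82 against 13.18 ± 3.39, a difference of 5.91. Mir124a-1hg, the host gene of a neuronal microRNA, was detected in 6 and 13 cells (3.97). Nlgn2, a postsynaptic adhesion protein, was detected in 4 and 11 cells (4.45), the amyloid precursor-like gene Aplp1 in 3 and 9 (4.66) and the neural splicing regulator Srrm4 in 2 and 9 (3.91). The Myc antagonist Mxd4 (2 and 8 cells, 4.20), the kinesin light chain Klc4 (1 and 8 cells, 5.19), the peptide transporter Slc15a2 (2 and 8 cells, 4.69), the phosphatidylinositol synthase Cdipt (3 and 10 cells, 4.20), the proton pump subunit Atp6v1c1 (4 and 10 cells, 4.04), Fam118b (0 and 8 cells, 3.93) and the atypical chemokine receptor Ackr1 (4 and 9 cells, 3.84) completed the group. Of all 24 genes, 22 differed by more than the larger of the SDs over cells, and 24 had the same sign in both array sets. Both counts were favoured by the choice of these genes for the size of their differences in the same cells. Mir124a-1hg differed by 0.18 in the high and by 6.33 in the low 18S set, and the other 11 by 2.15 (Srrm4) to 7.84 (Meg3) and by 3.15 (Atp6v1c1) to 5.90 (Slc15a2). Cdipt differed by 2.51 over cells with a Gapdh ratio of at most 3. With the mean of all probe sets, Meg3 differed by 2.04, Klc4 by 2.59, Nlgn2 by 2.29, Mxd4 by 2.06, Srrm4 by 1.51 and Slc15a2 by 1.46, and 3 probe sets of Meg3 had the opposite sign near background. With medians over cells, Slc15a2 differed by 8.70, Aplp1 by 8.12, Atp6v1c1 by 7.67, Mxd4 by 7.47, Ackr1 by 7.35 and Srrm4 by 5.93, and without a floor Fam118b by 6.14.

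**Figure D2:**
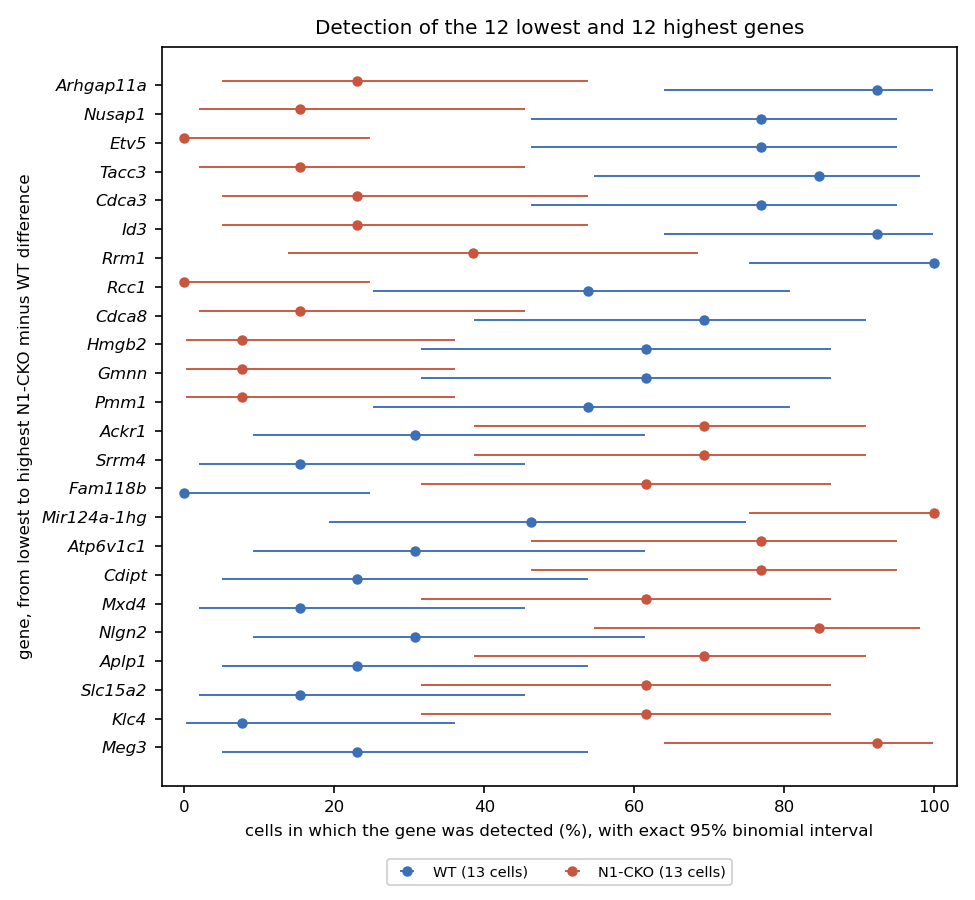
Share of WT and of N1-CKO cells in which each of the 12 lowest and 12 highest genes was detected (horizontal axis, percent of 13 cells), with exact 95% binomial intervals as bars. For 10 of the 24 genes the intervals of the groups do not overlap; these genes were picked for the size of their differences.

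Transcripts of Notch receptors and effectors had lower means in N1-CKO cells for 13 of 14 members, with a median of -1.89 at percentile 0.01 of random lists (central 95% of -0.97 to 0.70). WT cells had a median of 6 members detected (3 to 11) and N1-CKO cells 3 (0 to 7). Of the transcriptional repressors that Notch signalling induces, Hes1 was detected in 6 WT and 1 N1-CKO cells, with 9.21 ± 2.77 against 6.25 ± 2.10, and Hey1 in 6 and 0 cells, with 8.66 ± 3.33 against 5.64 ± 1.58. Hes5 was detected in 8 and 6 cells and differed by -1.97, less than its spread between cells. Besides Id3, Id1 (10 and 5 cells) differed by -3.51, and Id2 was detected in 2 and 0 cells. The remaining members were Dtx4 (-2.99), Hey2 (-2.10), Notch2 (-1.81), Rbpj (-1.64), Heyl (-1.61), Nrarp (-1.06) and the coactivator gene Maml1 (1.03, detected in 1 and 2 cells). Rbpj, the DNA-binding partner of the Notch intracellular domain, had another probe set with a difference of 1.56 (3 and 7 cells), so that its direction is not settled. The list's median was -0.73 in the high 18S set, inside the random range (percentile 6.39), and -3.28 in the low 18S set. In the high 18S set Heyl (2.08) and Nrarp (1.58) had the opposite sign, Hes5 (-0.04) and Hey2 (-0.02) hardly differed and Dtx4 differed by -0.52, whereas Hes1 (-1.88), Hey1 (-2.40) and Id1 (-2.12) were lower. With the limit on the Gapdh ratio it was -1.72 (percentile 0.02), with Dtx4 at -1.95, Heyl at -0.85, Nrarp at -0.11 and Maml1 at 1.78.

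Neuronal genes were higher in N1-CKO cells. Of 13 general neuronal and synaptic genes, 10 had higher and 3 lower means, with a median of 1.87, above all 10000 random lists (central 95% of -0.98 to 0.74), and N1-CKO cells had a median of 8 members detected (3 to 11) against 5 in WT (2 to 10). The synaptic vesicle calcium sensor Syt1 was detected in 4 WT and 9 N1-CKO cells, with 7.73 ± 3.44 against 11.30 ± 2.73. The neuronal tubulin Tubb3 was detected in 5 and 9 cells (3.19), the vesicle protein genes Syp in 3 and 6 (2.55) and Sv2b in 1 and 4 (2.16). Within the high 18S set the median was 0.30, inside the random range (percentile 61.4), and within the low 18S set 1.81. The median was 1.48 (percentile 99.8) with the limit on the Gapdh ratio, with Syt1 at 2.16 and Syp at 4.40. With the mean of all probe sets it was 0.51 and inside the random range, and with all members on the array 1.03.

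Proneural factors and Notch ligands were higher for 9 of 10 members, but their median of 0.69 was inside the random range (percentile 96.2). Neurod1, a basic helix-loop-helix factor of photoreceptor and amacrine precursors, was detected in 9 WT cells and in all 13 N1-CKO cells, with 11.61 ± 3.56 against 14.28 ± 1.07. The ligand genes Dll3 (0 and 3 cells, 2.88) and Dll4 (1 and 3 cells, 1.19) were seen in few cells. Hes6, which counteracts Hes1, was detected in 10 and 11 cells and differed by 0.93. The list's median was 0.58 in the high 18S set, 0.82 in the low 18S set, where it lay above the random range (percentile 97.9), and 0.65 over cells with a Gapdh ratio of at most 3 (percentile 92.3). It also lay outside the random range with the higher floor (0.82), with the mean of all probe sets (0.63) and with all members on the array (0.63), and ranged from 0.42 to 0.998 with 1 cell left out.

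**Figure D3:**
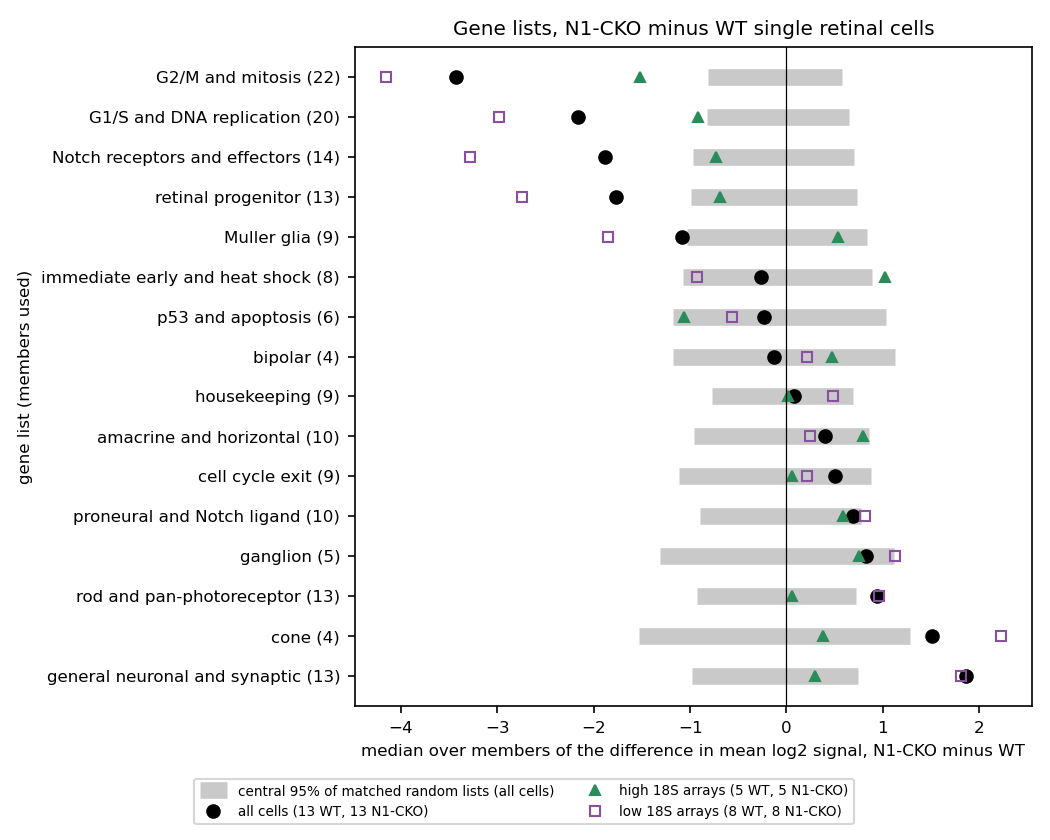
Median difference in mean log2 signal (N1-CKO minus WT, horizontal axis) over the members of 16 gene lists (vertical axis, number of members in brackets), for all cells (circles), high 18S arrays (triangles) and low 18S arrays (squares); grey bars are the central 95% of matched random lists for all cells. Circles lie outside their bar for 8 lists; against random lists drawn within each set, 2 lists were outside the range in the high and 9 in the low 18S set.

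Retinal progenitor genes had a median difference of -1.77 (percentile 0.03, central 95% of random lists -0.99 to 0.73), with 11 of 13 members lower in N1-CKO cells. WT cells had a median of 8 members detected (4 to 12) and N1-CKO cells 5 (3 to 11). The mRNA-decay factor gene Zfp36l1 was detected in 11 WT and 4 N1-CKO cells, with 12.23 ± 2.74 against 8.14 ± 3.21. The LIM homeobox gene Lhx2 was detected in 12 and 5 cells (-3.88), and Car2, a carbonic anhydrase, in 11 and 6 cells (-2.45). Ccnd1, the main D cyclin of the retina, was detected in 13 and 10 cells, with 15.12 ± 0.79 against 12.02 ± 3.87. Zfp36l1, Lhx2 and Ccnd1 differed by -4.09, -3.58 and -3.68 in the high 18S set and by -4.10, -4.06 and -2.74 in the low 18S set. As a list, progenitor genes were inside the random range in the high 18S set (-0.69, percentile 10.4) and below it in the low 18S set (-2.74). The list was inside the range as well over cells with a Gapdh ratio of at most 3 (-0.69, percentile 11.7), and the mean of all probe sets gave -1.07.

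Müller glia genes, many of which progenitors also express, had a median of -1.09 (percentile 1.92, central 95% of random lists -1.03 to 0.84), with 7 of 9 members lower in N1-CKO cells. Gpr37 was detected in 9 WT and 3 N1-CKO cells (-3.08), the intermediate filament gene Vim in 12 and 9 (-2.35), Dbi in 12 and 12 (-1.66) and Sox9 in 5 and 2 (-1.49). The list was 0.53, the opposite sign, in the high 18S set and -1.85 in the low 18S set. Limiting the Gapdh ratio to at most 3 gave -0.85, inside the random range (percentile 8.42), with Vim at -1.05, Sox9 at -0.72 and Dbi at -2.86. It was -0.72 without WT cell 2, -2.02 with medians over cells, and inside the random range (percentile 2.59) without probe sets marked as shared between transcripts.

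Photoreceptor genes were higher in N1-CKO cells as a group. Of 13 rod and pan-photoreceptor genes, 9 had higher and 4 lower means, with a median of 0.94 (percentile 99.4, central 95% of random lists -0.93 to 0.73). N1-CKO cells had a median of 7 members detected (1 to 13) and WT cells 4 (1 to 10). Otx2, required for photoreceptor fate, was detected in 7 WT and 11 N1-CKO cells, with 10.11 ± 4.42 against 12.73 ± 3.74. Prdm1, which holds photoreceptor precursors from bipolar fate, was detected in 4 and 10 cells (2.57), and the photoreceptor factor Crx in 6 and 10 cells (2.22). These differences lie within the spread between cells. Nrl, the rod-determining factor, named after its values were seen, was detected in 9 and 9 cells and differed by -0.34. The rod phosphodiesterase subunit gene Pde6g was detected in 1 and 3 cells (1.91). Cone genes had a median of 1.51 over 4 members (percentile 98.9), with the cone transducin beta subunit Gnb3 in 4 and 9 cells (3.12), Ccdc136 in 7 and 10 (1.85), Rxrg in 1 and 3 (1.17) and Gngt2 in 2 and 3 (0.67). The other 9 of the 13 cone genes measured were not detected in at least 2 cells. Among them, Thrb, Opn1mw, Arr3, Pde6h and Pde6c were detected in 0 and 0 cells, and Opn1sw and Gnat2 in 0 and 1. The median thus rests on 4 genes and does not show the cone list as a whole higher.

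Both photoreceptor lists depended on the cells included. In the high 18S set rod and pan-photoreceptor genes had a median of 0.06 (percentile 53.05) and cone genes 0.38 (percentile 55.9), against 0.96 and 2.23 in the low 18S set, where both lay above the random range. The medians over cells with a Gapdh ratio of at most 3 were 1.64 (above all random lists) and 1.75 (percentile 98.9), with Pde6g at 3.06, Rxrg at 2.20 and Gngt2 at 0.01. The rod and pan-photoreceptor median was 0.23 without N1-CKO cell 10, 0.48 without N1-CKO cell 2, 1.54 without WT cell 11 and 1.43 without WT cell 13. Without WT cells 1 and 2 it was 0.43 and the cone median 1.11, and with medians over cells 0.64 and 1.33, all inside the random range. With all members on the array the cone median was 0.16, inside the random range (percentile 70.1), and the rod and pan-photoreceptor median 0.51, above it (percentile 99.5). Cone members detected in at least 6 cells had a median of 2.48.

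**Figure D4:**
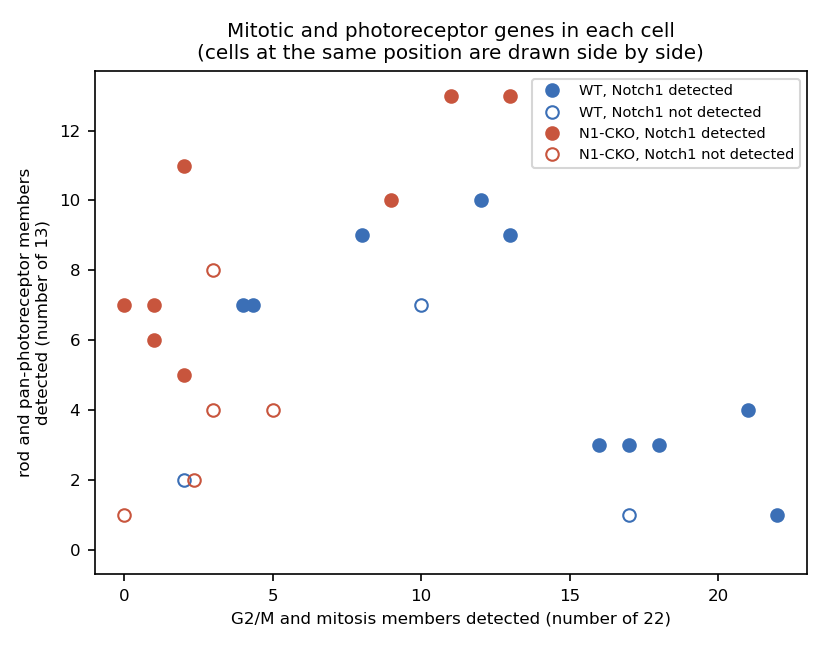
G2/M and mitosis members detected (horizontal axis, of 22) against rod and pan-photoreceptor members detected (vertical axis, of 13) in each cell; colour gives the group and filled symbols mark cells with Notch1 detected. The cells with at least 9 photoreceptor members were WT cells 10, 11 and 13, with 13, 8 and 12 G2/M members, and N1-CKO cells 1, 2, 3 and 10, with 9, 11, 13 and 2.

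Lists of other retinal neurons did not stand apart from random lists. Bipolar genes had a median of -0.13 and a mean of 0.45 over 4 members (percentile 36.6), with the LIM homeobox gene Lhx4 at 2.90 (1 and 5 cells), Prkca at -0.85, Pcp2 at -0.54 and Irx6 at 0.28, whose sign turned with quantile normalization (-0.23). Amacrine and horizontal genes had a median of 0.40 over 10 members (percentile 82.9), with the glycine transporter gene Slc6a9 at 1.88 (1 and 4 cells), Prox1 at 1.57, Onecut2 at 1.02 and Gad2 at 0.85. Ganglion cell genes had a median of 0.83 over 5 members (percentile 92.4), with Stmn2 at 2.04 (3 and 7 cells), Ebf3 at 1.70, Gap43 at -1.21 and Nefl at 0.83, and -0.09 with quantile normalization. Within the sets, the medians were 0.47 and 0.21 for bipolar, 0.79 and 0.24 for amacrine and horizontal, and 0.76 and 1.13 for ganglion cell genes, in the high and low 18S set. With the limit on the Gapdh ratio they were 0.22, 0.44 and 1.31, each inside the random range. With 1 cell left out they ranged from -0.31 to 0.24, from 0.12 to 0.69 and from 0.36 to 1.36. Onecut2 was -0.01 and Nefl -0.09 with quantile normalization.

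Markers of cells outside the neural retina were nearly absent from the detected transcripts of both groups. In at least 2 cells, 0 of 10 microglia and macrophage genes, 0 of 11 pigment epithelium and lens genes and 0 of 4 astrocyte genes measured were detected. The only endothelial and pericyte gene detected in at least 2 cells was Kdr, a VEGF receptor gene that retinal progenitors also express, in 9 WT and 3 N1-CKO cells (-2.38). The only erythroid gene was Hba-a1, in 1 and 1 cells.

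Among genes of cell cycle exit, members went both ways. Their median was 0.51 over 9 genes (percentile 87.3), with 6 higher and 3 lower in N1-CKO cells. The stress and growth-arrest gene Gadd45a was detected in 1 WT and 6 N1-CKO cells, with 5.48 ± 2.16 against 8.93 ± 3.36, and the antiproliferative gene Btg2 in 7 and 11 cells (1.68). The cyclin-dependent kinase inhibitors Cdkn1b (11.89 ± 1.52 against 9.89 ± 2.52) and Cdkn1c (5 and 1 cells, -1.96) were lower. The list's median was 0.06 in the high and 0.22 in the low 18S set, 0.48 over cells with a Gapdh ratio of at most 3, and -0.99 with medians over cells. Leaving out 1 cell at a time gave -0.07 to 0.76.

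Genes of cell death and of dissociation stress did not stand apart. The p53 and apoptosis list had a median of -0.23 over 6 members (percentile 35.1), with Ccng1 at -1.77 (4 and 0 cells), Bcl2l11 at -1.26, Trp53inp1 at 0.45 and Bbc3 at 0.34, which was -0.15 with quantile normalization. Immediate early and heat shock genes, which dissociation can induce, had a median of -0.26 over 8 members (percentile 32.6), with Ier2 at -1.40, Fos at -1.09 (10 and 8 cells), Junb at -0.80 and Dnajb1 at 0.72. With medians over cells this list was 0.75 (percentile 92.6), of opposite sign. It was 1.02 in the high and -0.93 in the low 18S set, and the p53 list -1.06 and -0.56. Limited to Gapdh ratios of at most 3, they were -0.29 and 0.49, the latter of opposite sign to that of all cells, and with 1 cell left out they ranged from -0.44 to 0.02 and from -0.47 to 0.07. Housekeeping genes had a median of 0.08 and a mean of -0.11 over 9 members, with Rps3 at 0.62, Eef1a1 at 0.49, Rpl13a at 0.49 and Hprt (9 and 7 cells) at -2.23. Their median was -0.20 with quantile normalization and -0.05 with scaling to the 75th percentile. Both groups had a median of 9 of the 9 housekeeping members detected, and the median was 0.02 in the high and 0.48 in the low 18S set.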

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

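The array sets, the limit on the Gapdh ratio and the treatment of members detected in 0 cells of a group were alternatives chosen after seeing the data; the others were planned. No paired analysis was possible because the results come from no test and the numbers only name cells. Of the 16 list medians, 8 lay outside the random range in all cells; these 8 kept their sign in all 11 alternatives other than the array sets and the limit on the Gapdh ratio, under that limit, and when each cell was left out in turn. Beyond the spread between cells, the list of Notch receptors and effectors moved to -3.28 in the low 18S set and general neuronal and synaptic genes to 0.30 in the high 18S set, while Müller glia genes reversed to 0.53 in the high 18S set. With medians over cells, G1/S and DNA replication moved to -3.85 and cell cycle exit to -0.99, and with the mean of all probe sets general neuronal and synaptic genes moved to 0.51. The cause was not tested. Over the cells left out in turn, the G2/M list ranged from -3.89 to -3.12, G1/S from -2.56 to -1.86, Notch receptors and effectors from -2.32 to -1.62, retinal progenitor genes from -2.20 to -1.39, Müller glia genes from -1.47 to -0.72, neuronal genes from 1.40 to 2.12, rod and pan-photoreceptor genes from 0.23 to 1.54 and cone genes from 1.03 to 2.02. Notch1 ranged from -2.26 to -1.17 over the cells left out and from -1.58 to -0.89 over the other planned settings. The 24 highest and lowest genes kept their sign in all 37 settings run for each, which their choice for large differences in these cells made likely. Of the 96 named genes, 11 had the opposite sign in the high and 1 in the low 18S set. Under the limit on the Gapdh ratio, retinal progenitor genes (-0.69) and Müller glia genes (-0.85) came inside the random range, and Notch1 differed by -0.09. Over the settings other than leaving out a cell, single gene differences moved by less than the spread between cells in 1029 cases and by more in 16. That spread is wide, with SDs of 3.06 and 4.21 for Notch1, so the count is lenient. A difference can change sign and still move by less than it. With other detection thresholds, 140 shares of cells stayed inside their intervals and 10 did not, and 42 differences in members per cell moved by less than the spread and 6 by more. The median difference of genes detected in at least 2 cells was -0.04 as deposited, -0.02 with quantile normalization, -0.13 with 75th percentile scaling, 0.18 in the high and -0.15 in the low 18S set; over all genes on the array it was 0.05. Dim arrays and amplification from 1 cell limit detection, so a transcript not detected may still have been present.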

Other observations

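The lists of FGF and ERK targets and of endoplasmic reticulum chaperones were made after Etv5 and Hspa5 were seen to be low, and the tests of weaker amplification, of animals or sessions, of background and of probe position, like the split into array sets, the limit on the Gapdh ratio and the use of the cell cycle exit list, were chosen after the results were seen. Etv5 belongs to the genes induced by FGF signalling through ERK. Without Etv5, 6 other such targets were detected in at least 2 cells, 5 lower and 1 higher in N1-CKO cells, with a median of -1.20, below the central 95% of random lists (-1.13 to 1.00). Etv4 (4 WT and 0 N1-CKO cells, -2.07), Spry1 (3 and 0 cells, -3.03) and Dusp6 (4 and 3 cells, -1.76) were lower, whereas the phosphatase gene Dusp4 (4 and 8 cells, 2.47) was higher. A hypothesis is that FGF target transcripts may be lower together in N1-CKO cells. It rests on 6 genes seen in few cells. The median lay inside the random range in the high 18S set (-0.64, percentile 12.0) and over cells with a Gapdh ratio of at most 3 (-0.94, percentile 5.95). In the low 18S set it was -1.91. A set effect shared by both groups would cancel, since each set holds both in equal numbers, but the difference varied between the sets. In the low 18S set the ratio of the Cre to the bioD control also differed between most WT cells and the N1-CKO cells. An effect that the groups do not share is therefore not excluded there. RNA quality is not ruled out.

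Hspa5, the main chaperone of the endoplasmic reticulum, was named after its values were seen. It was detected in 12 WT and 6 N1-CKO cells, with 12.62 ± 1.77 against 8.26 ± 3.62. Manf (11 and 6 cells, -2.79) and Hsp90b1 (11 and 7 cells, -1.92) were lower as well. The 12 other chaperone and stress genes, however, were split into 7 lower and 5 higher, among them Calr (0.19) and P4hb (0.91). Their median of -0.82 was inside the random range (-0.94 to 0.75), so these data do not show the chaperones lower together. In the high 18S set 9 of 12 were lower and the median was -1.16, at the edge of the random range (percentile 2.57, lower limit -1.17), in the low 18S set it was -0.67 (percentile 26.7), and over cells with a Gapdh ratio of at most 3 it was -0.41 (percentile 28.0).

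The lower signal of mitotic genes in N1-CKO cells was weighed against technical sources. The array set, as the 18S signal splits it, is argued against as the whole source, since each set holds both groups in equal numbers. A difference in handling or hybridisation between the groups inside the low 18S set is not excluded. There the ratio of the Cre to the bioD control was 1.49 to 1.75 in WT cells 1 to 7 but 1.07 to 1.47 in N1-CKO cells. The list's median also stayed below the random range in the high 18S set, where it was closest to it (-1.52). The 5 and 5 cells there overlapped, with 4 to 17 members detected in WT and 1 to 13 in N1-CKO cells. Cell cycle genes can rise and fall together within cells, so their median may leave the random range more easily, here and below. Which cells happened to be picked is therefore not excluded as a source. The lower RNA quality of some N1-CKO cells, as the Gapdh ratio measures it, is argued against as the whole source too. Over cells with a Gapdh 3'/5' ratio of at most 3 the median was -2.79, below the random range there (-0.94 to 0.66). This limit keeps unequal numbers of low 18S cells (6 WT, 3 N1-CKO). The 5 and 5 high 18S cells, with the median of -1.52, all had Gapdh ratios from 1.42 to 2.53. The Actb ratio does not always follow the Gapdh ratio. It was 54.8 in WT cell 2 and 12.7 in N1-CKO cell 11, which the limit keeps, so RNA quality as a whole is not excluded. Quantile normalization gives all arrays the same distribution. It took ganglion cell genes from 0.83 to -0.09, but that median is the value of Nefl, detected in 1 and 1 cells and near the floor. The shift therefore says little about brighter genes. General neuronal and synaptic genes went from 1.87 to 1.42. Quantile normalization left the mitotic median at -3.32, below all random lists matched on expression. Since all arrays then had the same distribution, a difference in that distribution is argued against as the whole source, and nothing further. Transcripts lost in a weak amplification are not brought back by this step, so a weaker amplification of N1-CKO cells is not excluded. Differences between animals or picking sessions cannot be told apart from the deletion, because 0 of the 26 samples have labels that name an animal, litter or session. Effects of the plasmids, Cre itself among them, cannot be told apart from it by design, because only N1-CKO cells received Cre. An earlier exit of N1-CKO cells from the cell cycle stays a hypothesis that the exit list does not decide, as its median of 0.51 lay inside the random range and ranged from -0.07 to 0.76 with 1 cell left out, with Gadd45a higher and Cdkn1b and Cdkn1c lower.

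Notch1 signal in N1-CKO cells was weighed in the same way. Background on dim arrays is argued against, since 8 of the 8 N1-CKO cells with Notch1 detected at the 90th percentile of their array were also above the 95th percentile. 2 readings would need the position of the probe sets: transcript that still carries the probed 3' end after deletion, and transcript left from before it. The other probe set, with a difference of -1.27, may lie on either side of the deleted part, and these readings cannot be told apart here. Cells in which recombination had not happened could give the same values, although the reporter needs Cre to be expressed.

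Mitotic and photoreceptor transcripts were compared within cells. N1-CKO cells 1, 2 and 3 had 9, 11 and 13 of 22 G2/M members with 10, 13 and 13 of 13 photoreceptor members; these were the N1-CKO cells with the most G2/M members. By the same rule, WT cells 2, 5 and 3 had 22, 21 and 18 G2/M members with 1, 4 and 3 photoreceptor members. Cells with both kinds were not limited to N1-CKO: WT cells 10, 11 and 13 had 13, 8 and 12 G2/M members with 9, 9 and 10 photoreceptor members, and N1-CKO cell 10 had 2 with 11. These cells were singled out after their values were seen.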
